A study of Mus musculus with 12 samples.

How the data were processed

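RNA was measured by poly(A) RNA sequencing in the spleen and in the axillary lymph node of mice of 2 genotypes, with 3 libraries in each of the 4 groups. Per the labels' protocols, RNA was extracted with a silica column kit, libraries were made with the Illumina RNA-Seq sample preparation kit, and the series design names the Genome Analyzer IIx as the sequencer. The submitters' processing notes name Trimmomatic for trimming, Bowtie and TopHat as aligners, Cuffdiff, and the mouse build GRCm38 (mm10). Their versions, the gene annotation, the program that counted reads and its strand setting are not given in the sources used here. Reads from overlapping or antisense genes, and from near-identical copies such as a gene and its processed pseudogene, could therefore have been divided in a way that cannot be checked from the tables.

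The deposited tables, one per tissue, hold 23284 gene symbols in the same order, with raw read counts per library, per the file headers. Beside the counts they hold the authors' comparison of the genotypes. It gives the authors' FPKM value of each group, the log2 ratio of these values, a p-value, a q-value and a yes or no call. The authors' log2 column holds very large numbers where one group has a value of 0, and was used only for genes with a finite value. The header does not say which genotype is the first group, so the 4 columns of group FPKM values were not used here. The sign of the authors' log2 ratios was read from their correlation with the edgeR log2 fold changes, which makes the first group DKO in lymph node and the libraries labelled DKO/hA-I in spleen (Pearson r across genes, which are not independent replicates, -0.993 and 0.945). All columns of counts were matched to a library through the animal code in its description.

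Total counts ran from 5911835 (lymph node DKO replicate 2) to 11950825 (lymph node DKO replicate 3). A floor of 3 counts corresponds to 0.507 and 0.251 CPM, counts scaled to library size, in these libraries. Intervals and floors given here cover counting error only, since reads without molecular identifiers are not independent molecules. Within each group, the counts of any pair of libraries differed by 10 to 59.9 times the Poisson expectation (chi-square per degree of freedom), so no library was a copy of another. The labels give each library its own animal code, and p-values measure the spread between these libraries.

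Genes were tested with edgeR 4.0.16 in R 4.3.3. Within each tissue, genes passing filterByExpr (minimum count 10, minimum total count 15) were kept, library sizes were scaled with TMM, and the quasi-likelihood test (robust estimateDisp and glmQLFit, then glmQLFTest) compared DKO minus DKO/hA-I. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. CPM values are on the TMM scale unless given as counts, errors of CPM are SDs over n = 3 libraries, and errors of log2 fold changes are standard errors. The tissue difference is the DKO minus DKO/hA-I contrast in lymph node minus that in spleen, in one fit of all 12 libraries. A set of 18 gene lists and 20 cell type marker lists, fixed before the data were examined, was tested with limma 3.58.1 camera at a preset correlation of 0.01 where at least 5 members were tested. The lists were tested again with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance without comparing them with other genes. Counts of members past the threshold over all genes tested are given beside those adjusted over the list alone.

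Genes named in the text follow a rule fixed before the data were examined. It takes Apoa1 and Apoe, the 12 higher and 12 lower called genes of largest fold change per tissue with non-overlapping groups and a mean of at least 1 CPM in the higher group. It also takes up to 4 called members of each list by adjusted p, otherwise up to 2 members as values, and the 5 genes of lowest adjusted p per direction for the tissue difference. Immunoglobulin and T cell receptor segments and gene model numbers were passed over, 23 of them among the higher and 27 among the lower lymph node calls. The text names most of the genes the rule takes, and the choice among them was made after their values were seen. A few of them are not reported here, for reasons other than their values. All genes the rule takes, with the genes the authors called in spleen, entered the comparison of settings and the test of the tissue difference. Genes singled out for other reasons are said to be so. Identifiers and coordinates come from GENCODE vM21 on GRCm38, to which 20873 of the 23284 symbols matched (89.6%).

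The steps were tested on simulated counts with the means and library sizes of the real libraries and 200 changed genes. The changed genes were drawn from the better covered genes only, so recovery of genes with few counts was not measured. For spleen, edgeR recovered 85% of genes changed 2-fold and 99% of genes changed 4-fold. For lymph node it recovered 57% and 95%, and for the tissue difference 34% and 81%, with 6.60%, 5.59% and 4.96% false calls in the 3 comparisons. Alternatives were DESeq2 1.42.0, limma voom with sample weights, RLE size factors, other low count filters and all 12 libraries in the fit. Others were removal of immunoglobulin and haemoglobin genes before scaling, the test without robust estimation, the replicate number as a block, the animal code as a block in spleen, and leaving out each library. In lymph node the middle number of the animal code separates the genotypes, so no such block was fitted there. An effect of what this number marks cannot be told apart from that of genotype in lymph node. Added after the data were seen were an adipocyte score as a covariate in lymph node, exchanged genotype labels in spleen, the animal code block for the spleen lists, and the replicate block for genes called in both tissues. Figures were drawn with matplotlib 3.10.9.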

Results

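Mice lacking both apoE, the ligand through which remnant lipoproteins are cleared, and apoA-I, the main protein of high density lipoprotein (DKO), were compared with DKO animals that carry excess apoA-I of human origin (DKO/hA-I). All mice were 30 weeks old and fed normal laboratory diet. Spleen and axillary lymph node were sequenced from 3 libraries per genotype, and the animal codes differ between the tissues. Spleen libraries held 8966001 to 11237680 counts and lymph node libraries 5911835 to 11950825. The comparisons ask which genes of each lymphoid tissue differ when human apoA-I is absent, and whether the tissues differ in this.

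The mouse Apoa1 gene (chromosome 9, 46228580 to 46230466, GRCm38) had 0 to 13 counts per library. Its sum over the group was 27 in spleens labelled DKO, 19 in spleens labelled DKO/hA-I, 9 in DKO nodes and 6 in DKO/hA-I nodes. Apoe (chromosome 7, 19696109 to 19699188) stood at 11.5 ± 3.13 CPM against 10.4 ± 1.85 in spleen (DKO against DKO/hA-I, log2 fold change 0.14 ± 0.22, edgeR adjusted p = 0.943). In lymph node it stood at 14.6 ± 5.2 CPM against 8.4 ± 0.574 (log2 fold change 0.82 ± 0.28, adjusted p = 0.126). Both genes are targeted in both genotypes, and human APOA1 was not analysed here, so these genes do not test the genotype labels.

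In spleen, edgeR without a block called 1 gene between the genotypes, the processed pseudogene Rpl31-ps12 (chromosome 16, 16819749 to 16820123, minus strand). It derives from the gene of a protein of the large ribosomal subunit. It stood at 0.174 ± 0.0671 CPM against 65.7 ± 11.7 in the libraries labelled DKO and DKO/hA-I (log2 fold change -8.48 ± 0.29, adjusted p = 1.12e-06). The summed counts were 5 and 2162, a ratio of 382 with a 95% counting interval of 163 to 1178. In lymph node the same pseudogene differed in the opposite direction, with 2094 counts in DKO and 3 in DKO/hA-I libraries, so the directions below are those of the labels in both tissues, and those of a tissue would turn if its labels were exchanged. The parent gene Rpl31, singled out for that reason, stood at 539.8 ± 141 CPM against 407 ± 44.6 (log2 fold change 0.41 ± 0.18, edgeR adjusted p = 0.929) in spleen and 445 ± 90.6 CPM against 479 ± 10.1 (log2 fold change -0.11 ± 0.16, edgeR adjusted p = 0.734) in lymph node, and how reads were divided between gene and pseudogene cannot be checked from the tables. Of 14009 spleen genes tested, 617 had an unadjusted p under 0.05, against 700 by chance, and 1478 genes (10.6%) had non-overlapping groups, against 10% by chance. DESeq2 also called 1 gene and limma voom 164, 62 higher and 102 lower. With the animal code as a block edgeR called 515 genes, and without DKO replicate 1 it called 167.

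**Figure D1:**
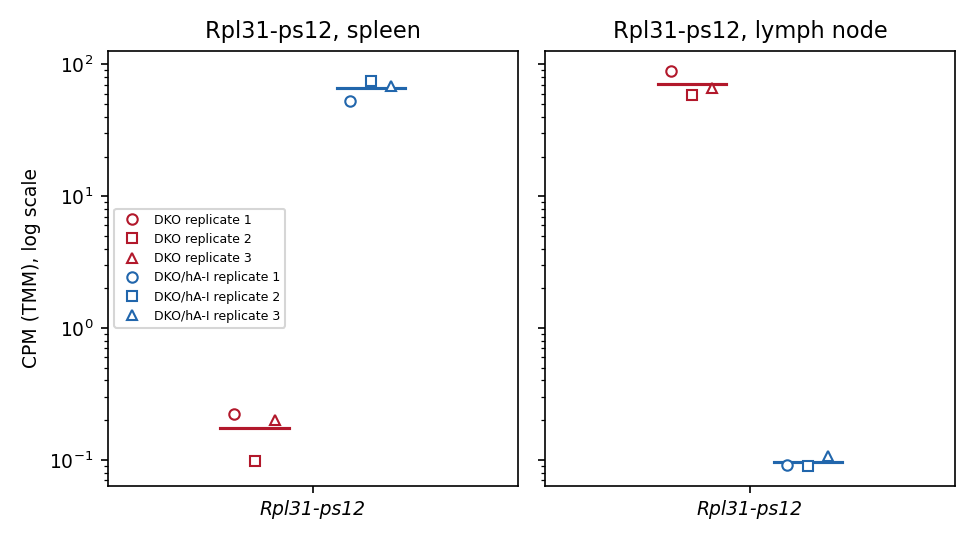
CPM of Rpl31-ps12 (log axis) in the 6 spleen and 6 lymph node libraries, with symbols for the replicates and a line at each group mean. Spleen libraries labelled DKO/hA-I average 65.7 CPM and DKO nodes 71.4 CPM, while both other groups lie under 1 CPM.

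In spleen, 9 of 35 tested lists passed the camera threshold, 6 higher and 3 lower in spleens labelled DKO. With an estimated correlation no list passed (smallest adjusted p = 0.714), nor with fry (smallest adjusted p = 0.80), and no member of any list was called by edgeR. All 19 immediate early and heat shock genes had a positive log2 fold change, with a median of 0.42 (camera adjusted p = 5.07e-11, and 0.714 with an estimated correlation) and 1 member past the threshold adjusted over the list alone. Dusp1, a phosphatase that ends MAP kinase signalling, stood at 73.7 ± 20.3 CPM against 42.7 ± 1.06, and Fos, a subunit of the AP-1 transcription factor, at 17.9 ± 4.57 CPM against 10.8 ± 2.26. The chaperone genes Hspa1a and Hspa1b, called in the authors' deposited table and singled out for that reason, reached 178 and 80.4 CPM of Hspa1b in DKO replicates 1 and 3. DKO replicate 2 stood at 5.65 CPM and the DKO/hA-I spleens at 5.49 to 11.8 CPM.

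The plasma cell list had 17 of 18 members with a positive log2 fold change (median 0.24, camera adjusted p = 3.06e-10, and 0.714 with an estimated correlation), and 3 passed when adjusted over the list alone. Its leading members were endoplasmic reticulum genes, Creld2 at 109 ± 11.4 CPM against 72.8 ± 7.35 and Sdf2l1 at 76 ± 2.88 CPM against 54.4 ± 5.93. Erythroid markers had a median of 0.65 (adjusted p = 0.0023, and 0.915 with an estimated correlation). The red cell membrane genes Epb4.2 stood at 172 ± 89.8 CPM against 99.3 ± 17.2 and Rhd at 165 ± 94.1 CPM against 93.8 ± 18.1. Haemoglobin transcripts made up 3.06 ± 1.92% of counts in spleens labelled DKO and 2.10 ± 0.573% in those labelled DKO/hA-I, from 1.14% in DKO replicate 1 to 4.98% in DKO replicate 2. For cell cycle genes the median was 0.27 (adjusted p = 0.00283, and 0.915 with an estimated correlation). Mcm5 stood at 217 ± 79.6 CPM against 161 ± 21.2 and Foxm1 at 57.2 ± 14 CPM against 47.4 ± 2.48. Without DKO replicate 2 the cell cycle list was at 0.02 (adjusted p = 0.992) and the erythroid list at 0.24 (adjusted p = 0.753). Oxidative phosphorylation genes had a median of 0.15 (adjusted p = 0.00309, and 0.915 with an estimated correlation) and cytosolic ribosomal protein genes 0.10 (adjusted p = 0.0148, and 0.915 with an estimated correlation). For oxidative phosphorylation, camera adjusted p was 0.753 without DKO replicate 2. For ribosomal proteins it was 0.755 without DKO replicate 2 and 0.51 without DKO/hA-I replicate 1, and for cell cycle it was 0.992 without DKO replicate 2 and 0.623 without DKO/hA-I replicate 2. Adjusted over the list alone, 0 members of these 4 lists passed. Without DKO replicate 1 the medians were 1.02 for the erythroid, 0.49 for the cell cycle, 0.26 for the oxidative phosphorylation and 0.16 for the ribosomal list, and without DKO replicate 2 the last 2 were 0.04 and 0.01. The cell cycle median was 0.44 and 0.12 without DKO/hA-I replicates 1 and 2, and the ribosomal one 0.04 without DKO/hA-I replicate 1.

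The lists lower in spleens labelled DKO were cholesterol synthesis, NK cell markers and marginal zone B cell markers. For cholesterol synthesis, 18 of 22 members had a negative log2 fold change (median -0.16, adjusted p = 0.00309, and 0.915 with an estimated correlation), with the sterol enzymes Hsd17b7 at 7.25 ± 0.966 CPM against 10 ± 2.52 and Sc5d at 17.8 ± 0.924 CPM against 22.1 ± 3.67. NK cell markers had a median of -0.24 (adjusted p = 0.014, and 0.915 with an estimated correlation), led by the receptor genes Klra8 at 4.18 ± 1.55 CPM against 7.35 ± 1.04 and Klra9 at 2.16 ± 0.102 CPM against 3.35 ± 0.971. All 8 marginal zone B cell markers had a negative log2 fold change (median -0.08, adjusted p = 0.036, and 0.915 with an estimated correlation). Cd1d1 stood at 62.5 ± 1.12 CPM against 77.1 ± 8.31 and the complement receptor gene Cr2 at 518 ± 111 CPM against 684 ± 83. Adjusted over the list alone, 0 members of these 3 lists passed. The cholesterol median was -0.10 without DKO replicate 3 and -0.10 and -0.26 without DKO/hA-I replicates 1 and 2, and the NK cell median -0.15 without DKO replicate 2. The marginal zone B cell median was -0.19 without DKO replicate 1 and -0.20 without DKO/hA-I replicate 1. Camera adjusted p for cholesterol synthesis was 0.0509 without DKO replicate 1, 0.183 without DKO/hA-I replicate 1 and 0.0636 without DKO/hA-I replicate 3. For NK cells it was 0.0942 without DKO replicate 1, 0.168 without DKO replicate 2 and 0.0614 without DKO/hA-I replicate 1. For marginal zone B cells it was 0.118 without DKO replicate 2, 0.133 without DKO replicate 3, 0.148 without DKO/hA-I replicate 2 and 0.316 without DKO/hA-I replicate 3. With the animal code as a block none of the 3 lists passed (adjusted p = 0.0821 for cholesterol synthesis, 0.0821 for NK cell and 0.0593 for marginal zone B cell markers). Lists of lipid-laden macrophage genes (median -0.01, adjusted p = 0.694) and LXR targets and cholesterol efflux (median 0.03, adjusted p = 0.673) did not pass. Among their members the lipid-binding gene Fabp4 stood at 5.45 ± 1.43 CPM against 9.41 ± 2.62, the elastase gene Mmp12 at 3.77 ± 1.4 CPM against 6.51 ± 0.508. Cd5l stood at 610.3 ± 79.7 CPM against 513 ± 70.8 and the phospholipid transfer gene Pltp at 83.4 ± 2.57 CPM against 73.3 ± 7.18.

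The remaining 24 spleen lists that were tested did not pass. Adjusted p was 0.759 for the type I interferon response (Oasl1 25.2 ± 4.95 CPM against 19.6 ± 1.12, Bst2 136 ± 34.3 CPM against 103 ± 16.8), 0.338 for the interferon gamma response, 0.759 for MHC class II presentation and 0.994 for inflammatory cytokines and chemokines (Ccl8 8.01 ± 2.91 CPM against 3.93 ± 2.44, Ccl2 2.66 ± 2.67 CPM against 0.814 ± 0.216). It was 0.347 for T cell activation, 0.489 for regulatory T cells (Foxp3 25.1 ± 4.61 CPM against 18.9 ± 2.29), 0.606 for germinal centre genes, 0.161 for complement and phagocyte receptors (Marco 246 ± 22.6 CPM against 199 ± 24.6) and 0.994 for extracellular matrix. Among cell type markers it was 0.0625 for B cells (Ms4a1 377 ± 83.6 CPM against 457 ± 37.3), 0.0985 for T cells, 0.171 for CD8 T cells, 0.171 for red pulp macrophages, 0.282 for monocytes (Ccr2 56.1 ± 15.5 CPM against 92.5 ± 23.5) and 0.171 for neutrophils (Csf3r 98 ± 25.4 CPM against 138 ± 13.7). It was 0.994 and 0.171 for conventional and plasmacytoid dendritic cells, 0.694 for megakaryocytes, 0.716 for mast cells and basophils, 0.759 for reticular stroma, 0.0782 for endothelium, 0.759 for adipocytes, 0.694 for skeletal muscle and 0.759 for nerve. Skin and mammary epithelium and exocrine pancreas had fewer than 5 tested markers in either tissue, and 0 of the 12 immunoglobulin constant genes were tested. Adjusted over the list alone, 0 members of these lists passed, except 1 lower skeletal muscle gene. With the animal code as a block, the type I interferon response passed (adjusted p = 1.71e-05, higher). Median and camera direction differed in sign for extracellular matrix, conventional dendritic cell, adipocyte and skeletal muscle lists, and median and mean for inflammatory cytokines and reticular stroma. Without DKO replicate 1, camera adjusted p was 2.28e-06 for type I interferon response and 0.0162 for B cell. Without DKO replicate 2, camera adjusted p was 0.0432 for interferon gamma response, 0.0432 for T cell activation and effector, 0.0088 for T cell and 0.0432 for endothelium. Without DKO replicate 3, camera adjusted p was 0.0196 for T cell, 0.00614 for neutrophil and 0.00614 for megakaryocyte and platelet. Without DKO/hA-I replicate 1, camera adjusted p was 0.000426 for B cell and 0.0215 for endothelium. Without DKO/hA-I replicate 2, camera adjusted p was 0.00545 for germinal centre and follicular helper, 0.00472 for T cell and 0.0448 for red pulp macrophage. Without DKO/hA-I replicate 3, camera adjusted p was 0.0382 for interferon gamma response, 0.00332 for T cell activation and effector, 0.0184 for germinal centre and follicular helper, 0.0382 for complement and phagocyte receptors, 0.000272 for monocyte and 2.41e-06 for neutrophil.

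The spleen count depended on how single libraries and the animal code were treated. Leaving out DKO replicate 1 gave 167 calls, 150 higher and 17 lower, and leaving out DKO replicate 2 gave 2. The animal code as a block, in which DKO replicate 1 has a code of its own, gave 515 calls, 355 higher and 160 lower. The time of day at which tissues were taken is not given in the sources used here. The authors' deposited table called 8 spleen genes, of which Rpl31-ps12 was also called by edgeR. The others were Hspa1a, Hspa1b, Hsph1, Dnajb1 and Dnaja1, all chaperones or their partners, with Cyr61 and Apol11b. Their log2 ratios in that table, DKO minus DKO/hA-I, ran from 1.06 for Apol11b to 3.43 for Hspa1b.

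**Figure D2:**
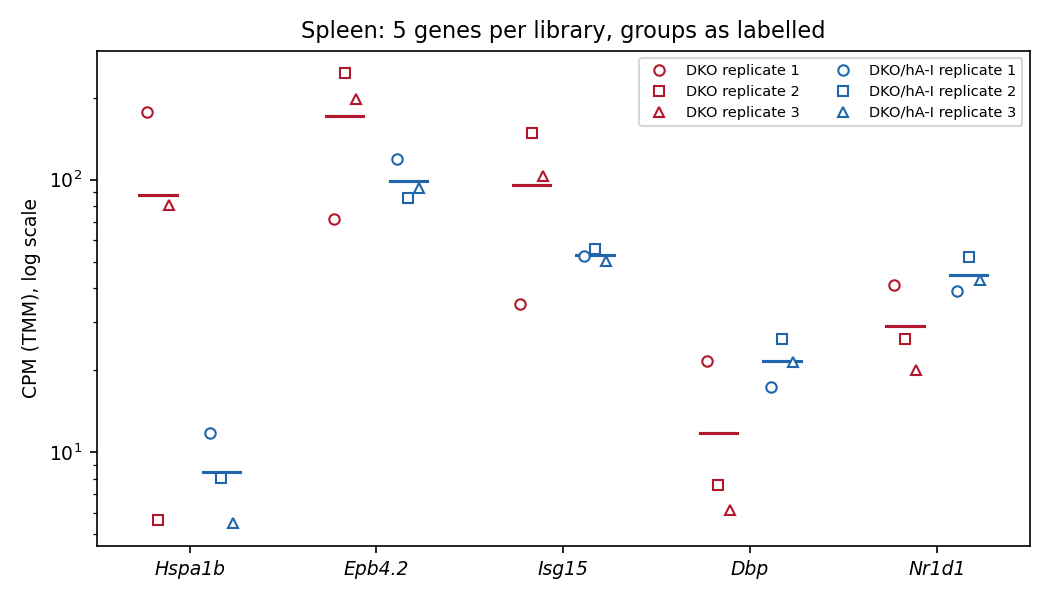
CPM (log axis) of 5 genes in the 6 spleen libraries, with symbols for the replicates and a line at each group mean. For Hspa1b the DKO libraries range from 5.65 to 178 CPM. Dbp and Nr1d1, genes of the circadian clock, are lower in DKO replicates 2 and 3 than in the other 4 libraries.

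In lymph node, DKO and DKO/hA-I stand for the labels of the libraries, as in spleen. The lists of lipid-laden macrophage genes, extracellular matrix and complement and phagocyte receptors passed the camera threshold as higher in DKO than in DKO/hA-I nodes, and adipocyte markers as lower, while 2 complement and phagocyte receptor genes and 1 lipid-laden macrophage gene were lower. With an estimated correlation none of the 4 lists passed (adjusted p = 0.331 for each of the first 3 and 0.271 for adipocyte markers). Spp1, which encodes the secreted matrix protein osteopontin, stood at 202 ± 122 CPM against 6.56 ± 2.37 (log2 fold change 4.94 ± 0.50, edgeR adjusted p = 0.00756). Trem2, a lipid-sensing receptor of macrophages, stood at 102 ± 75 CPM against 4.4 ± 0.571 (log2 fold change 4.55 ± 0.71, adjusted p = 0.017). Adipoq, which encodes the adipocyte hormone adiponectin, stood at 2.59 ± 1.44 CPM against 101 ± 67.6 (log2 fold change -5.38 ± 0.64, adjusted p = 0.00993). In all, 962 of 14012 genes were called, 553 higher and 409 lower in DKO, of which 376 and 313 differed at least 2-fold. The DKO nodes share a middle number of the animal code that no DKO/hA-I node has. A genotype effect and an effect of whatever that number marks therefore cannot be told apart in lymph node.

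The 12 called genes with the largest fold changes upwards were led by Rpl31-ps12 (71.4 ± 16.4 CPM against 0.0961 ± 0.00952, log2 fold change 9.37 ± 0.33, with 3 counts in DKO/hA-I and a count ratio of 772, 95% interval 264 to 3747). Next came Tmem178 (12.2 ± 8.88 CPM against 0.222 ± 0.134), Spp1, Rag1, a recombinase gene of developing lymphocytes (13.8 ± 10.1 CPM against 0.464 ± 0.222), Trem2 and Gpnmb, a glycoprotein of foam cells and osteoclasts (1529 ± 1017 CPM against 69.4 ± 16). The stromelysin gene Mmp3 (195 ± 71.6 CPM against 9.27 ± 1.45) and Rhov (2.51 ± 1.56 CPM against 0.12 ± 0.137) followed. The others were the cathepsin gene Ctsk (252 ± 180.5 CPM against 13.4 ± 1.51), Rnf128 (39.9 ± 29.6 CPM against 2.15 ± 0.417), Slc9a4 (8.3 ± 5.27 CPM against 0.487 ± 0.194) and Mamdc2 (41.6 ± 29.7 CPM against 2.44 ± 0.256). Their log2 fold changes after Rpl31-ps12 lay between 4.10 and 5.73.

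The 12 called genes with the largest fold changes downwards included genes of adipocytes. Cidea, a lipid droplet protein of brown fat, stood at 1.99 ± 2.06 CPM against 151 ± 75.3 and Otop1 at 0.373 ± 0.294 CPM against 19.3 ± 7.85. Cox8b stood at 0.523 ± 0.352 CPM against 30.8 ± 16.1, Adig at 0.202 ± 0.126 CPM against 13.4 ± 7.77, Aldh1a7 at 0.399 ± 0.425 CPM against 16.3 ± 7.68 and Lctl at 0.174 ± 0.177 CPM against 9.25 ± 9.0. Their log2 fold changes lay between -6.17 and -5.58. Bpifb3 had 0 counts in DKO and 66 in DKO/hA-I libraries, at least 19.9-fold lower against a floor of 3 counts over the group. Others had 1 to 3 counts in DKO, and the ratio of DKO/hA-I to DKO counts was 103 (95% interval 28.2 to 856) for the fibroblast growth factor co-receptor Klb and 60.6 (95% interval 20.4 to 296) for Lep, the leptin gene. It was 86.8 (95% interval 15.2 to 3463) for Sec14l4, 67.2 (95% interval 22.7 to 328) for Gldn and 56.5 (95% interval 15.3 to 472) for Rgs7.

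Of 34 lymph node lists tested, 20 passed the camera threshold, 11 higher and 9 lower in DKO. With an estimated correlation none passed (smallest adjusted p = 0.271). By fry 6 passed: adipocyte, red pulp macrophage, reticular stroma, plasmacytoid dendritic cell, endothelium and erythroid markers.

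The lipid-laden macrophage list had 14 of 20 members higher and 1 lower (17 and 1 adjusted over the list alone), with a median log2 fold change of 1.89 (camera adjusted p = 3.04e-14, and 0.331 with an estimated correlation). Besides Spp1, Trem2 and Gpnmb it holds Fabp4, the lower member, at 74.1 ± 18.4 CPM against 704 ± 346, a gene that adipocytes also express and that the adipocyte list shares. Complement and phagocyte receptors had 12 of 21 higher and 2 lower (17 and 2 over the list alone), with a median of 0.99 (camera adjusted p = 9.51e-11, and 0.331 with an estimated correlation). The complement genes C1qa (628 ± 255 CPM against 155 ± 26.5) and C4b (573 ± 63.7 CPM against 246 ± 25.9) and the Fc receptor gene Fcgr3 (158 ± 61.1 CPM against 34.3 ± 3.34) rose, while the scavenger receptor gene Marco fell (22.9 ± 10.1 CPM against 282 ± 109, log2 fold change -3.62 ± 0.41). Red pulp macrophage markers, which share the C1q genes, had 4 of 14 higher (10 over the list alone) and a median of 1.16 (camera adjusted p = 1.94e-07, and 0.271 with an estimated correlation). C1qb stood at 688 ± 313 CPM against 159 ± 29, C1qc at 557 ± 234 CPM against 149 ± 28.5 and the efferocytosis receptor Mertk at 139 ± 41.6 CPM against 44.4 ± 9.15. The LXR list had 2 of 14 higher, Pltp (616 ± 307 CPM against 98.7 ± 28.8) and Mertk, and 1 lower, the desaturase Scd1 (822 ± 50.9 CPM against 7298 ± 2888), which adipocytes also express. Its median was 0.63 (camera adjusted p = 0.0244, and 0.658 with an estimated correlation), with 8 higher and 1 lower over the list alone. Camera adjusted p was 0.0758 without DKO replicate 1, 0.0531 without DKO replicate 3, 0.0594 without DKO/hA-I replicate 2 and 0.477 without DKO/hA-I replicate 3.

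Extracellular matrix genes had 10 of 18 higher (15 over the list alone), with a median of 1.47 (camera adjusted p = 6.24e-13, and 0.331 with an estimated correlation). Among them were fibronectin Fn1 (387 ± 183 CPM against 81.9 ± 19.2), Thbs1 (117 ± 23.2 CPM against 40.3 ± 2.81), the metalloproteinase inhibitor Timp1 (9.4 ± 6.47 CPM against 0.806 ± 0.232) and the basement membrane collagen Col4a2 (233 ± 70.9 CPM against 94.6 ± 15.6). Reticular stroma markers had 5 of 11 higher (6 over the list alone) and a median of 0.88 (camera adjusted p = 2.89e-05, and 0.271 with an estimated correlation). Bst1 stood at 67.5 ± 2.64 CPM against 36.7 ± 3.4, podoplanin Pdpn at 39.5 ± 17.3 CPM against 10.3 ± 0.649, Pdgfra at 116 ± 25.5 CPM against 54 ± 4.95 and Pdgfrb at 87.4 ± 23.1 CPM against 37.2 ± 0.765. Inflammatory cytokines and chemokines had 5 of 21 higher (12 over the list alone) and a median of 1.14 (camera adjusted p = 4.66e-06, and 0.331 with an estimated correlation). The B cell attractant Cxcl13 stood at 347 ± 119 CPM against 137 ± 2.48, and the interleukin-1 antagonist Il1rn at 67 ± 37.9 CPM against 14.2 ± 5.53. Ccl12 stood at 31.5 ± 3.75 CPM against 18.9 ± 1.38 and Ccl4 at 5.51 ± 0.125 CPM against 1.96 ± 0.761.

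**Figure D3:**
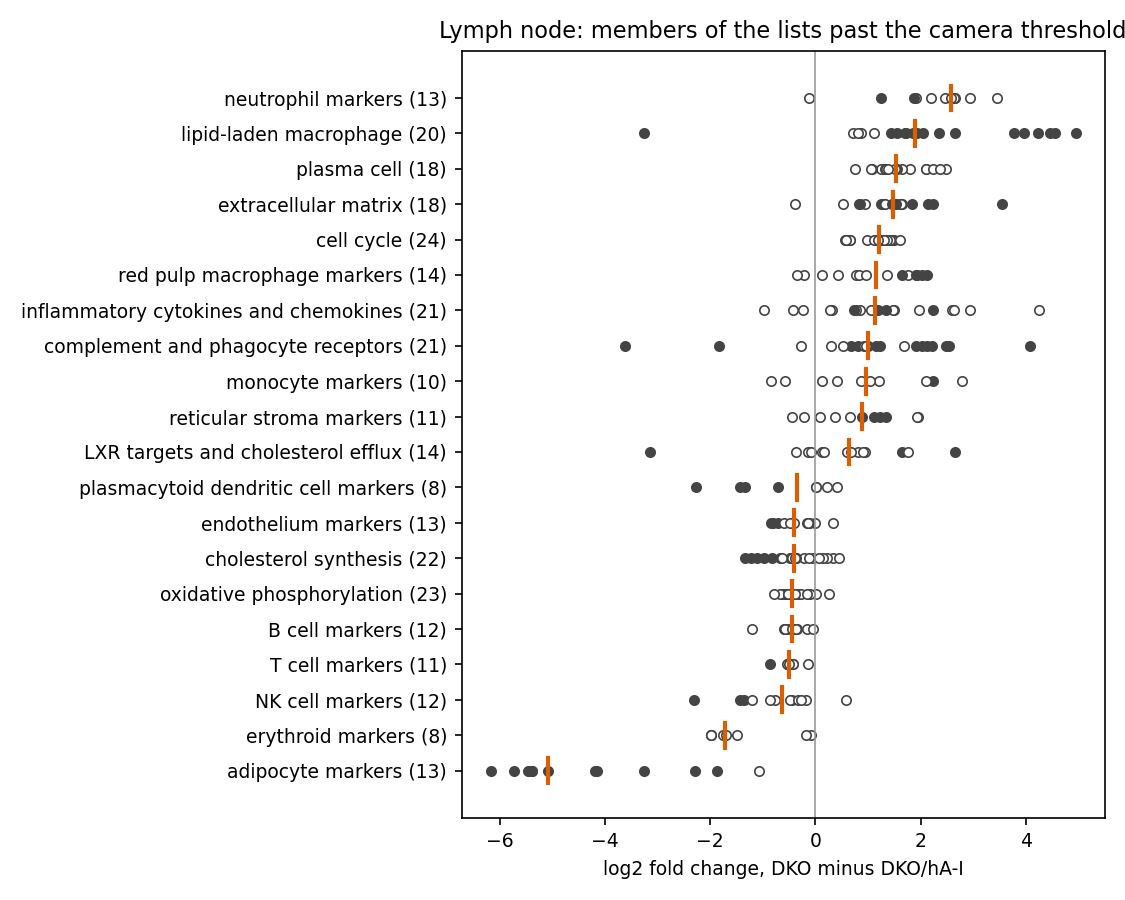
Log2 fold change (DKO minus DKO/hA-I) in lymph node of each tested member of the 20 lists past the camera threshold, with the number of members in brackets. Filled points are called genes, open points are not, and the bar is the list's median, from -5.08 for adipocyte markers to 2.57 for neutrophil markers.

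Adipocyte markers had 12 of 13 members lower, also over the list alone, with a median of -5.08 (camera adjusted p = 1.37e-25, and 0.271 with an estimated correlation). Besides Adipoq and Cidea, the gluconeogenic enzyme Pck1 stood at 6.73 ± 4.47 CPM against 274 ± 74.6 and the lipid droplet coat gene Plin1 at 2.63 ± 1.21 CPM against 86 ± 45.4. These markers made up 0.0226 ± 0.00135% of counts in DKO and 0.241 ± 0.111% in DKO/hA-I nodes, where the libraries ranged from 0.120% to 0.338%. Cholesterol synthesis had 6 of 22 lower (7 over the list alone) and a median of -0.41 (camera adjusted p = 0.000445, and 0.515 with an estimated correlation). Hmgcs1 stood at 38.8 ± 4.67 CPM against 68.9 ± 9.35, Acat2 at 23.5 ± 6.2 CPM against 50.2 ± 13.3 and Pmvk at 16.9 ± 2.1 CPM against 27.1 ± 2.93. Oxidative phosphorylation had 0 of 23 called and a median of -0.44 (camera adjusted p = 7.00e-05, and 0.521 with an estimated correlation). Ndufv2 stood at 55.8 ± 8.19 CPM against 81.5 ± 9.07. With the adipocyte score of each library as a covariate, which nearly follows genotype, 0 genes were called in lymph node, and 163 of the 962 turned sign. Under it the medians of the cholesterol and oxidative phosphorylation lists turned to 0.79 and 0.75. That of the lipid-laden macrophage list was 1.70 (camera adjusted p = 0.0137) and that of the extracellular matrix list 2.38 (camera adjusted p = 1.58e-07). With this covariate 26 lists passed, 13 in each direction, against 20 without it, so passing says little about a single list. The cholesterol median was -0.65 without DKO replicate 2 and -0.26 without DKO/hA-I replicate 2.

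The lists of plasmacytoid dendritic cell, NK cell, T cell, B cell, endothelium and erythroid markers passed the camera threshold as lower in DKO nodes, none of them with an estimated correlation. Plasmacytoid dendritic cell markers had 4 of 8 lower, also over the list alone, and 4 with a positive log2 fold change (median -0.35, camera adjusted p = 0.000425, and 0.271 with an estimated correlation). Siglech stood at 16.7 ± 4.14 CPM against 79.8 ± 16.4, the chemokine receptor Ccr9 at 7.16 ± 0.966 CPM against 18.2 ± 2.31, Pacsin1 at 22.7 ± 1.54 CPM against 37.2 ± 4.67 and Klk1 at 1.94 ± 0.607 CPM against 5.1 ± 0.45. NK cell markers had 3 of 12 lower (6 over the list alone; median -0.63, camera adjusted p = 0.000115, and 0.331 with an estimated correlation), namely Ncr1 (4.83 ± 0.877 CPM against 13.1 ± 0.506), granzyme A Gzma (2.03 ± 0.969 CPM against 9.66 ± 2.01) and Klra8 (1.64 ± 0.522 CPM against 4.29 ± 0.537). T cell markers had 1 of 11 lower (6 over the list alone; median -0.51, camera adjusted p = 0.000154, and 0.515 with an estimated correlation), the transcription factor Tcf7 (174 ± 21.9 CPM against 317 ± 53). All 12 B cell markers had a negative log2 fold change with 0 called (3 lower over the list alone; median -0.45, camera adjusted p = 0.00053, and 0.515 with an estimated correlation). Fcer2a stood at 191 ± 72.7 CPM against 443 ± 94.2 and Cr2 at 276 ± 53.8 CPM against 415 ± 44.5. Endothelium markers had 3 of 13 lower (5 over the list alone; median -0.40, camera adjusted p = 0.00449, and 0.35 with an estimated correlation), the receptors Kdr (84.1 ± 5.54 CPM against 151 ± 33.8), Lyve1 (122 ± 24.4 CPM against 211 ± 20.6) and Tek (13.4 ± 0.727 CPM against 22 ± 2.67). Erythroid markers had 0 of 8 called (median -1.72, camera adjusted p = 0.00701, and 0.271 with an estimated correlation). Hba-a1 stood at 23.3 ± 12.5 CPM against 91.6 ± 71.5, and haemoglobin transcripts made up 0.0602% of counts in DKO/hA-I replicate 2 against 0.0190% in each other DKO/hA-I node. Without that library the erythroid median was -1.14 (camera adjusted p = 0.00688). The B cell median was -0.28 without DKO replicate 2, and the endothelium median -0.12, -0.20 and -0.22 without DKO replicates 2 and 3 and DKO/hA-I replicate 1.

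Plasma cell, cell cycle, neutrophil and monocyte lists also passed the camera threshold as higher in DKO nodes, none of them with an estimated correlation. Plasma cell genes had 1 of 18 called (2 over the list alone; median 1.52, camera adjusted p = 1.32e-05, and 0.521 with an estimated correlation), the syndecan gene Sdc1 (114 ± 48.7 CPM against 26.6 ± 8.03). Cell cycle genes had 0 of 24 called (21 over the list alone; median 1.21, camera adjusted p = 1.94e-07, and 0.519 with an estimated correlation). Foxm1 stood at 35.8 ± 17.4 CPM against 15.1 ± 2.12 and Pcna at 216 ± 55.5 CPM against 137 ± 9.07. Neutrophil markers had 2 of 13 called (7 over the list alone; median 2.57, camera adjusted p = 2.89e-05, and 0.515 with an estimated correlation), Mmp9 (46.6 ± 12.3 CPM against 12.6 ± 4.15) and Csf3r (82.3 ± 19.6 CPM against 34.7 ± 12.3). Monocyte markers had 1 of 10 higher, Fn1, which is also in the extracellular matrix list (5 higher and 1 lower over the list alone, median 0.96, camera adjusted p = 0.0378, and 0.39 with an estimated correlation). DKO replicate 2 held 6211 CPM of the antibody joining chain gene Igj, 844 of the proliferation gene Mki67 and 409.6 of the neutrophil gene S100a8, singled out after the values were seen, against at most 1632, 222 and 92.5 in the other lymph node libraries. Without it the medians were 0.38 for plasma cell (camera adjusted p = 0.00804), 0.52 for cell cycle (adjusted p = 0.000569), 1.10 for neutrophil (adjusted p = 0.0716) and 0.68 for monocyte markers (adjusted p = 0.204). The monocyte median was 0.59 without DKO replicate 3. Monocyte markers also lost their call without DKO/hA-I replicate 3 (adjusted p = 0.202). DKO replicate 2 had the lowest DKO values of Trem2 (21.8 CPM) and Gpnmb (357 CPM), both still above every DKO/hA-I library.

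The remaining lymph node lists did not pass, although some of their members were called. In T cell activation (adjusted p = 0.135; 3 higher, 1 lower of 25, and 6 and 2 over the list alone) the memory marker Cd44 (319 ± 39.9 CPM against 167 ± 19.7), the checkpoint genes Pdcd1 (21.5 ± 1.08 CPM against 10.7 ± 0.198) and Tigit (19.3 ± 1.95 CPM against 10.1 ± 2.35) rose and Gzma fell. In germinal centre genes (adjusted p = 0.0763; 2 of 13 higher, also over the list alone) S1pr2 (54.1 ± 14.4 CPM against 16.6 ± 3.53) and Pdcd1 rose. Marginal zone B cell markers (adjusted p = 0.79, with 3 higher and 1 lower of 8, and 3 and 2 over the list alone) included Cd1d1 (24.8 ± 5.62 CPM against 50.2 ± 5.34), which fell, and S1pr3 (108 ± 12.4 CPM against 64.3 ± 9.53), Cd9 (290.3 ± 154 CPM against 76.2 ± 6.27) and Myof (257 ± 149 CPM against 58.7 ± 4.6), which rose. Cd9, and Itgax given below, are also in the lipid-laden macrophage list. Immediate early and heat shock genes (adjusted p = 0.79; 3 of 19 higher, also over the list alone) included Atf3 (90.2 ± 65.4 CPM against 11 ± 2.16), Egr2 (40 ± 16.6 CPM against 13.8 ± 3.65) and Jund (113 ± 3.43 CPM against 82.5 ± 0.713). Single members were called in MHC class II presentation (adjusted p = 0.496; Ctss 1582 ± 684 CPM against 576 ± 70.6) and conventional dendritic cells (adjusted p = 0.836; Itgax 506 ± 344 CPM against 100.2 ± 13.9). The same held for regulatory T cells (adjusted p = 0.835; Gpr83 0.756 ± 0.0773 CPM against 2.75 ± 0.644) and nerve (adjusted p = 0.0735; S100b 0.261 ± 0.0811 CPM against 4.45 ± 3.81). Of 4 tested megakaryocyte markers, too few for a test, Pf4 was called (9.93 ± 6.2 CPM against 1.9 ± 1.08). Adjusted over the list alone, 1 megakaryocyte marker was higher and 1 lower, and 1 skin and mammary epithelium marker was higher. No member was called in the type I interferon response (adjusted p = 0.927; Ifi204 159 ± 13.8 CPM against 77.2 ± 33.3), the interferon gamma response (adjusted p = 0.384), or cytosolic ribosomal proteins (adjusted p = 0.384). Nor was any in CD8 T cells (adjusted p = 0.126; Gzmk 9.3 ± 4.54 CPM against 3.61 ± 0.267, Cd8b1 63.2 ± 22.2 CPM against 118 ± 7.75), mast cells (adjusted p = 0.734) or skeletal muscle (adjusted p = 0.384). Adjusted over the list alone, 1 CD8 T cell marker was higher and 2 were lower. Median and camera direction differed in sign for the type I interferon, immediate early and marginal zone lists, and median and mean for conventional dendritic cells. Without DKO replicate 1, camera adjusted p was 0.0205 for germinal centre and follicular helper, 0.0244 for cytosolic ribosomal proteins and 0.0337 for CD8 T cell. Without DKO replicate 2, camera adjusted p was 0.0129 for MHC class II presentation. Without DKO replicate 3, camera adjusted p was 0.00984 for germinal centre and follicular helper and 0.0418 for nerve. Without DKO/hA-I replicate 1, camera adjusted p was 0.0457 for T cell activation and effector and 0.0107 for nerve. Without DKO/hA-I replicate 2, camera adjusted p was 5.81e-05 for type I interferon response, 0.000154 for interferon gamma response and 0.0365 for CD8 T cell.

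**Figure D4:**
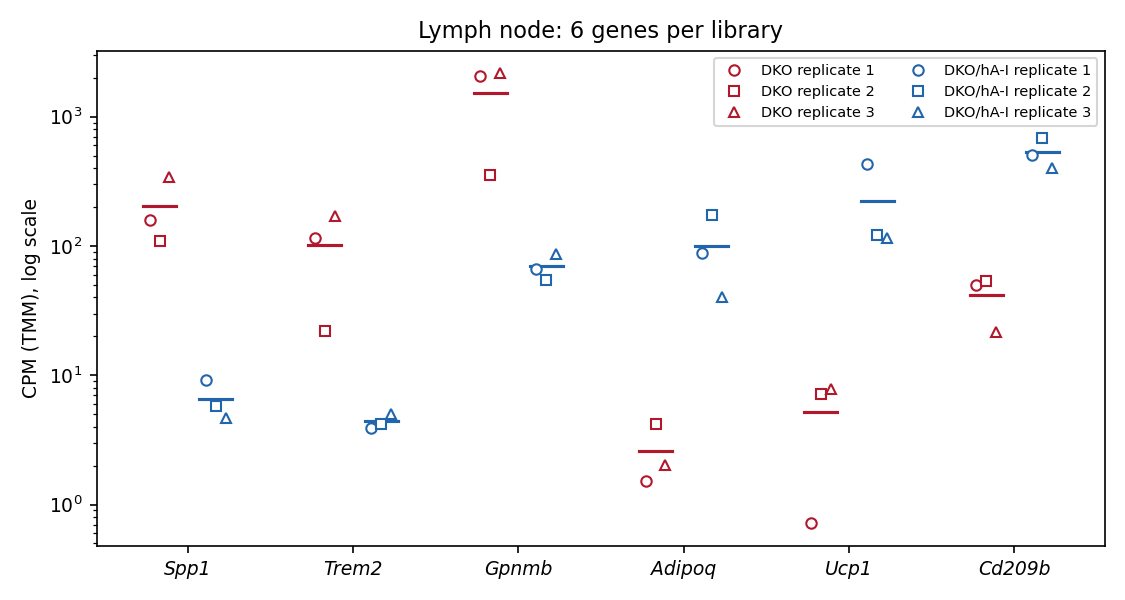
CPM (log axis) of 6 genes in the 6 lymph node libraries, with symbols for the replicates and a line at each group mean. Spp1, Trem2 and Gpnmb are higher in all 3 DKO libraries, and Adipoq, Ucp1 and Cd209b are lower in all 3.

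All 962 called lymph node genes had non-overlapping groups, as did 4262 of the 14012 genes (30.4%, against 10% by chance). The authors' deposited table called 784 genes, 513 higher and 271 lower in DKO, of which 514 were also called by edgeR, all in the same direction as oriented here. DESeq2 called 1982 genes and limma voom 2519, with 958 and 951 of the 962 among them in the same direction. Of the 962 genes, 114 to 919 stayed called in the same direction with 1 library left out. Leaving out 1 library gave 115 calls (without DKO/hA-I replicate 2) to 2245 calls (without DKO replicate 2), with 425 and 144 without DKO replicates 1 and 3 and 149 and 433 without DKO/hA-I replicates 1 and 3. The balance of directions turned as well, with 55 higher and 94 lower without DKO/hA-I replicate 1, 29 and 86 without DKO/hA-I replicate 2, 89 and 344 without DKO/hA-I replicate 3 and 71 and 73 without DKO replicate 3. Without DKO replicate 2, 1555 were higher and 690 lower.

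The genotype difference itself, as labelled, differed between the tissues for 487 of 14608 genes, 298 with a higher value in lymph node than in spleen and 189 with a lower one. Rpl31-ps12 led, with log2 fold changes of -8.48 ± 0.29 in spleen and 9.37 ± 0.33 in lymph node (tissue difference 17.84 ± 0.45, edgeR adjusted p = 1.73e-10). The prostaglandin transporter gene Slco2a1 had -0.08 ± 0.11 in spleen and 1.40 ± 0.15 in lymph node (adjusted p of the difference = 0.00271), and the chemokine receptor gene Ccr1 had -0.75 ± 0.25 and 2.06 ± 0.19. The Wnt antagonist gene Frzb had 0.23 ± 0.16 and 3.77 ± 0.42, and Rarres1 had -0.66 ± 0.27 and 2.60 ± 0.35. In the other direction, Ceacam2 (chromosome 7, 25516042 to 25539857) had 0.91 ± 0.16 in spleen and -1.97 ± 0.28 in lymph node (adjusted p of the difference = 0.00164), and the scavenger receptor gene Marco had 0.31 ± 0.12 and -3.62 ± 0.41. The mitochondrial carrier gene Ucp3 had 0.65 ± 0.29 and -4.38 ± 0.45, the potassium channel gene Kcnk3 0.14 ± 0.28 and -4.73 ± 0.45, and Siglech 0.17 ± 0.15 and -2.27 ± 0.22.

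Among 13518 genes tested in both tissues, 1 was called in spleen and 852 in lymph node, and the gene called in both, Rpl31-ps12, went in opposite directions, so 0 were shared in the same direction by edgeR and 0 by DESeq2. Independent lists would share 0.0242 genes in the same direction, and Fisher's exact test of the overlap in either direction gave a one-sided p of 0.063. With 1 gene called in spleen this is the lowest p the test can give, so it could not pass 0.05. The 852 lymph node genes had the same sign in spleen in 56.9% of cases. An unadjusted edgeR spleen p under 0.05 was found for 66 of them, and for 617 of all 14009 genes tested in spleen. The median absolute log2 fold change of the 852 genes was 1.30 in lymph node and 0.14 in spleen. They were selected by the lymph node test, which favours large values there, so these medians do not compare the tissues on equal terms. Leaving out 1 library moved the count of 487 to between 179 (without spleen DKO replicate 2) and 1160 (without lymph node DKO replicate 2). It was 188 without spleen DKO replicate 3 and 225, 196 and 199 without spleen DKO/hA-I replicates 1 to 3. It was 222 and 190 without lymph node DKO replicate 3 and DKO/hA-I replicate 2. The balance of directions was not kept either, with 170 higher and 301 lower without lymph node DKO/hA-I replicate 3 and 87 and 103 without lymph node DKO/hA-I replicate 2. It was 205 and 207, 83 and 96, and 94 and 94 without spleen DKO replicates 1, 2 and 3, and 94 and 102 without spleen DKO/hA-I replicate 2. Without spleen DKO replicate 1, 14 genes were called in both tissues in the same direction and 5, Rpl31-ps12 among them, in opposite directions.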

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

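Chosen after related results were seen were the tests of exchanged labels, of a variant with right labels, of the animal codes, of reads of the parent gene, of the amount of fat, of dilution by fat, of dissection and of heat shock genes. The genotype difference differed between the tissues for 487 genes by the test of the difference itself, and 58 of the reported genes that the naming rule takes are among them, 42 with a higher and 16 with a lower value in lymph node (largest adjusted p = 0.0463). Values in brackets below are the log2 difference, lymph node minus spleen, of DKO minus DKO/hA-I, as labelled. Of the 80 relabellings within tissues that were drawn, the real one included, 6 gave as many genes as the real labels, with 915 as the highest of the others, so chance is not excluded. All 5 that called more kept the real lymph node groups or their mirror. Drawn relabellings with those lymph node groups called 353 to 915 genes whatever the spleen split, and the others 0 or 1. The count thus followed the lymph node groups and was reached under other spleen labels as well. Draws that keep the lymph node groups do not test chance in the lymph node difference.

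With a higher value in lymph node were the lipid-laden macrophage list's Spp1 (4.49), Trem2 (4.61), Gpnmb (4.43) and Mmp12 (4.73), the complement, phagocyte receptor and red pulp macrophage lists' C1qa (1.83), C1qb (1.89), C1qc (1.65), C4b (1.23) and Fcgr3 (2.23), and the LXR list's Pltp (2.44) and Mertk (1.76). From the extracellular matrix list they were Fn1 (2.29), Thbs1 (1.41), Timp1 (3.62), Col4a2 (1.08) and Dcn (1.17), from reticular stroma Bst1 (0.89), Pdgfra (1.48) and Pdgfrb (1.26), from cytokines and chemokines Cxcl13 (1.56) and Il1rn (2.44), from neutrophil and monocyte markers Csf3r (1.71), Mmp9 (2.15) and Ccr2 (1.57), and from marginal zone B cell markers Cd9 (1.95) and Myof (2.31). Single members of other lists were Ctss (1.47), Itgax (2.45), Cd44 (0.87), S1pr2 (1.70), Sdc1 (1.73) and Pf4 (2.41). Taken by size or by the tissue difference were Mmp3 (3.54), Ctsk (3.81), Rag1 (5.89), Tmem178 (6.67), Rnf128 (4.26), Ccr1 (2.80), Frzb (3.51), Slco2a1 (1.45), Rarres1 (3.23) and Rpl31-ps12 (17.84). With a lower value in lymph node were Pck1 (-5.18), Fabp4 (-2.49), Scd1 (-3.08), Marco (-3.95), Siglech (-2.47), Ccr9 (-1.47), Gzma (-2.09), Ncr1 (-1.26) and Gpr83 (-2.37) from the lists, and Klb (-7.92), Aldh1a7 (-5.41), Ucp3 (-5.06), Kcnk3 (-4.89), Bpifb3 (-8.20), Rgs7 (-5.42) and Ceacam2 (-2.90) by size or by the tissue difference. Values of genes at 0 to 3 counts in a group, such as Bpifb3, Klb and Rgs7, depend on the prior count of the fit. Trem2 did not pass the low count filter in spleen alone, so its value rests on few spleen counts. The same may hold for others: 13 adipocyte markers were tested in lymph node and 5 in spleen. Cd9, Itgax and Ctsk are also in the lipid-laden macrophage list.

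Rpl31-ps12 was near 0 in opposite genotypes of the tissues, although in both tissues the libraries that hold it form the first group of the authors' comparison as read from the values, and the tissue difference of 17.84 argues against a variant carried with the genotype under right labels. A difference in read placement that applied to ribosomal protein pseudogenes in general is argued against, since 0 of the 5 others tested followed (largest absolute log2 fold change 0.23), as is a variant following the middle number of the animal code, since 2 of these codes in spleen hold libraries of both states. Placement on the pseudogene of reads of Rpl31 alone, also by a step that followed the order of those groups, stays open: where Rpl31-ps12 was high, Rpl31 was lower by 33.9 CPM (SE 52.6) in lymph node and by 133 CPM (SE 85.4) in spleen, and the pseudogene was higher by 71.3 and 65.5 CPM. Genotype labels exchanged in one tissue remain a possible explanation. Leaving out Rpl31-ps12 itself, 33.3% of the 3 genes with non-overlapping groups and at least 2-fold differences in both tissues went the same way, too few to decide. Of the 57 such genes with log2 differences of at least 0.5 in both tissues, 61.4% went the same way as labelled, and of all 429 non-overlapping genes 70.2%. Genes are not independent, and the share to be found without an exchange is not known, so these shares do not decide it. A variant that segregated in the colony apart from genotype was not tested and stays open as well.

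Adipocyte markers were lower in DKO nodes, 12 of them in every DKO library below every DKO/hA-I library. All called lymph node genes have such non-overlapping groups, so this is no test of whether those samples held less fat tissue, which stays open. Dilution by fat RNA would shift all other marker lists alike. TMM scaling takes out a shift shared by most genes (median of all genes 0.0146), so its size cannot be read from these fold changes. A shared shift does not account for the medians of 16 other marker lists, which span 4.29 on the log2 scale (from -1.72 for erythroid to 2.57 for neutrophil markers). The span was 2.74 without DKO replicate 2, the smallest with 1 library left out. Dilution as the only source of the genes higher in DKO is thus argued against. A difference in dissection and one in the animals cannot be told apart, since nothing in the files marks the dissection, and a genotype effect on fat stays open and untested. The share of adipocyte counts varied 2.81-fold among the DKO/hA-I nodes, and the lowest of them was 5.13 times the highest DKO node.

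Heat shock genes were high in 2 of the 3 spleens labelled DKO. An effect of genotype present in every DKO spleen would separate the groups, and 0 of the 5 chaperone genes in the authors' calls had non-overlapping groups. Between DKO libraries the smaller of the ratios for Hspa1a and Hspa1b was 27.6, against 2.14 for Hspa1b among DKO/hA-I libraries. This restates that the libraries differ, so handling before lysis and other differences between single animals cannot be told apart. An effect of genotype in some animals stays open.

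For the other counts, 3 libraries against 3 give 10 splits, too few for a share under 0.05. In spleen the real split called 1 gene and the highest other 92, and 3 of the 10 splits called at least 1 gene. That other split puts DKO replicate 1 with DKO/hA-I replicates 2 and 3, and what sets these libraries apart was not tested. In lymph node the real split called 962 genes and every other split 0, so 1 of the 10 reached the real count. For the lists, 8 of 10 spleen splits passed at least the real 9 (highest other 16) and 3 of 10 lymph node splits at least the real 20 (highest other 22). For genes called in both tissues in the same direction the real count is 0, which any relabelling reaches (100 of 100, highest other 3), so this count says nothing about chance.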

How the results depend on the processing

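Alternatives chosen after the results were seen are the adipocyte score as a covariate, the exchanged spleen labels, the animal code block for the spleen lists and the replicate block for genes called in both tissues. For spleen genes (1 called), limma voom gave 164, the animal code as a block 515, and leaving out each library 1 to 167. For lymph node genes (962 called), DESeq2 gave 1982, limma voom 2519, all 12 libraries in the fit 2253, the adipocyte score 0, and leaving out each library 115 to 2245. For the tissue difference (487 called), DESeq2 gave 962, exchanged spleen labels 753, and leaving out each library 179 to 1160. Genes called in both tissues in the same direction numbered 1 with exchanged labels and 0 to 14 with each library left out. In the setting with 14, another 5 went in opposite directions. For the lists, the estimated correlation gave 0 in both tissues (9 and 20 with the preset), and fry 0 in spleen and 6 in lymph node, while leaving out each library gave 7 to 13 in spleen and 18 to 22 in lymph node. The animal code block gave 7 in spleen, 7 higher and 0 lower (6 and 3 without it), and the adipocyte score 26 in lymph node, 13 in each direction (11 and 9 without it). The adipocyte score nearly follows genotype and leaves little to compare. Apart from the adipocyte score, the cause was not tested. In simulated data DESeq2 made 22.3% false calls in lymph node, limma voom 5.03% and edgeR 5.59%. The simulated spread was taken from edgeR's fit, so these rates do not compare the tools on equal terms. They do not show which of the larger call sets are false.

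The replicate numbers do not pair the libraries: same-numbered libraries had correlated deviations of -0.00959, 0.160 and -0.0874 in spleen and -0.137, 0.0775 and -0.0400 in lymph node, and not every library correlated best with its own number. Spleen pairs that share the middle number of the animal code had 0.348 (DKO replicate 3 with DKO/hA-I replicate 1), 0.160 and 0.0305 (DKO replicate 2 with DKO/hA-I replicates 2 and 3). The other spleen pairs lay between -0.318 and 0.0127. These values depend on each other, since deviations are taken from group means, and whether the code pairs the spleen libraries was not tested. With the replicate number as a block, 1 spleen gene, 438 lymph node genes (221 higher, 217 lower) and 152 genes of the tissue difference (76 higher, 76 lower) were called, with 0 in both tissues in the same direction, and 9 and 20 lists passed.

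With the adipocyte score, signs turned in lymph node for Lep (1.00), Lctl (1.43), Apoe (-0.068), Hmgcs1 (0.19), Acat2 (0.92), Fabp4 (0.45), Ifi204 (-0.62), Oas1a (-1.79), Tigit (-0.21), Ndufv2 (0.28), Ndufa4 (0.95), S1pr3 (-0.10), Hba-a1 (1.05), Alas2 (2.38) and Kdr (0.30), and for the cholesterol synthesis (0.79) and oxidative phosphorylation (0.75) lists. In spleen, signs turned for Vwf (-0.0911, with limma voom with sample weights), Mcpt8 (0.0927, with limma voom with sample weights) and Kcnk3 (-0.18, with the animal code as a block). With each spleen library left out, log2 fold changes that turned ran for Apoe from -0.0493 (without DKO replicate 2) to 0.32 (without DKO replicate 1), for Vwf from -0.00546 (without DKO replicate 2) to 0.41 (without DKO replicate 3), for Cfd from -0.29 (without DKO replicate 2) to 1.26 (without DKO replicate 1), for Cela1 from -0.0524 (without DKO replicate 2) to 0.46 (without DKO replicate 1), for Kcnk3 from -0.18 (without DKO replicate 1) to 0.33 (without DKO replicate 2). The median of the cell cycle list ran from 0.0232 (without DKO replicate 2) to 0.49 (without DKO replicate 1), with a test of opposite sign at the lowest. The cause was not tested. Of the named tissue differences, 188 of 190 alternative values kept their sign and their side of the threshold. The exceptions came with exchanged spleen labels, Rpl31-ps12 at 0.89 (adjusted p = 0.581) and Ceacam2 at -1.07 (adjusted p = 0.0527). These genes were taken for their low adjusted p, which favours staying past the threshold. Of all 487 calls, 170 (without spleen DKO replicate 2) to 482 (without lymph node DKO replicate 2) stayed called in the same direction with 1 library left out. With the replicate number as a block 143 did. No scaling moved the median of all genes by over 0.1 on the log2 scale. At this depth 2-fold changes were recovered in 57% of simulated lymph node genes, none of them genes with few counts, so a gene that was not called is not shown to be unchanged.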

Other observations

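The lists and genes in this part were chosen after the data were seen, so their counts and medians are descriptions of these libraries and not tests of a list. Of 11 sinus macrophage genes tested in lymph node, Marco, Cd209b, Cd209d and Timd4 were lower in DKO and 0 were higher (median -0.73). The lectin gene Cd209b, expressed by macrophages of the subcapsular sinus and medulla, stood at 41.8 ± 17.4 CPM in DKO against 531 ± 141 in DKO/hA-I nodes (log2 fold change -3.67, edgeR adjusted p = 0.00781), and at 36.6 ± 18.5 against 33.7 ± 9.39 in spleen. The members went both ways: Cd5l stood at 577 ± 107 CPM in DKO against 169.7 ± 145 (log2 fold change 1.76), Mrc1 at 141 ± 55.1 CPM in DKO against 68.2 ± 36.4 (log2 fold change 1.05) and Csf1r at 495 ± 89.4 CPM in DKO against 358 ± 42.4 (log2 fold change 0.47), none of them called, and Marco, Timd4, Cd5l and Cd163 are also in lists fixed before the data were examined. Lysosome genes, of which Ctsd, Ctsk, Npc2 and Lipa are also in the lipid-laden macrophage list and Ctss in that of MHC class II, had 14 of 24 members higher in DKO nodes and 0 lower (median 1.03). Fatty acid and triglyceride synthesis, which holds Scd1 of the LXR list, had 16 of 18 lower (median -3.20). Brown fat genes, of which Ucp1 and Cidea are also in the adipocyte list and Cox8b, Otop1 and Kcnk3 were already among the genes named, had 11 of 12 lower (median -4.92), with the uncoupling protein gene Ucp1 at 5.19 ± 3.89 CPM in DKO against 223 ± 181 in DKO/hA-I nodes. Lymphatic endothelium, which shares Lyve1, Prox1 and Flt4 with the endothelium list, Stab2 with the complement list and Madcam1 with reticular stroma, had 3 of 11 lower (median -0.14). In spleen, 0 members of these lists were called.

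In spleen, genes of the circadian clock output had a median log2 fold change of -0.43 over 7 genes, and in lymph node of -0.25, with 0 called in either tissue. The clock output gene Dbp stood at 21.6, 7.59 and 6.12 CPM in DKO replicates 1, 2 and 3 and at 17.3, 26.1 and 21.4 in DKO/hA-I replicates 1, 2 and 3. Nr1d1, a nuclear receptor of the clock, stood at 41.1, 26 and 20.1 CPM and at 39, 51.9 and 42.8 in the same order. In lymph node, in that order, Dbp stood at 11.4, 4.73 and 4.06 CPM and at 7.22, 5.75 and 5.78, and Nr1d1 at 43.1, 9.47 and 17.6 CPM and at 25, 41.5 and 22.2. The interferon-induced gene Isg15 was 34.9, 149 and 103 CPM in DKO and 52.3, 55.5 and 50.4 in DKO/hA-I spleens. Spleen DKO replicate 1 was thus near the DKO/hA-I spleens in the clock genes, and it carries an animal code whose middle number no other spleen library has. The time of day at which the spleens were taken is not given in the sources used here, and whether it differed between the animals was not tested.

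Lymph node DKO replicate 2 held 11130.0 CPM of the secreted protease inhibitor gene Slpi, against 239.9 and 772 in the other DKO nodes and 49.1 to 164 in DKO/hA-I nodes. Its epithelial marker gene Epcam was at 72.4 CPM, against 3.96 to 7.86 in the other 5 nodes.

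A few genes had like differences in both tissues as labelled. Syt12 had log2 fold changes of -1.59 ± 0.29 in spleen and -1.33 ± 0.33 in lymph node, Zc3h6 -0.90 ± 0.17 and -0.79 ± 0.20, and Gm4759 -0.88 ± 0.19 and -0.80 ± 0.17. Of these only Gm4759 in lymph node passed the threshold (edgeR adjusted p = 0.0335). Other genes went opposite ways. Leaving out Rpl31-ps12, 3 genes had non-overlapping groups and at least 2-fold differences in both tissues. Among them Syt12 alone went the same way. Col6a5 had log2 fold changes of -1.53 ± 0.44 in spleen and 4.30 ± 1.03 in lymph node, and Cpt1b 1.72 ± 0.73 and -4.21 ± 0.63. Across genes, which are not independent replicates, the signed statistics of the tissues had a Spearman correlation of 0.199 as labelled. Of the 10 splits of the spleen libraries, 2 gave a correlation of at least that size (largest other 0.211 in absolute size).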
